A study of Rattus norvegicus with 8 samples.

How the data were processed

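Colon RNA of female Wistar rats aged 14 weeks was measured on 8 Agilent 1-colour Cy3 arrays, with 2 arrays in each of 4 groups. Per the labels' protocols, diets were given for 8 weeks, and colitis was induced with 5% dextran sulfate sodium (DSS), a polymer that injures the colon lining, for 7 days. RNA of 6 rats was pooled, from 6 rats in the healthy group and 10 in each colitis group. The 2 healthy arrays therefore carry the same 6 rats. The labels do not say whether the 2 arrays of a colitis group carry the same pool or different pools. Different pools of 6 from 10 rats would still share rats. The arrays of a group are thus not independent sets of animals. The p-values measure only the spread between arrays, and how far that includes differences between animals is not known. All 8 arrays lay on 1 slide and were scanned once. The ALA and healthy arrays lay in row 1 of the slide and the fish oil and n-6 arrays in row 2. The ALA and fish oil arrays lay in columns 1 and 2, and the healthy and n-6 arrays in columns 3 and 4. In the comparisons of ALA with n-6, n-6 with healthy, ALA with fish oil and fish oil with healthy, slide row and group therefore cannot be told apart. In those of fish oil with n-6 and ALA with healthy, slide column and group cannot be told apart. None of the 6 comparisons is thus free of slide position.

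The scanner files hold spot intensity values that Agilent Feature Extraction 11.5.1.1 made, per the file headers. The processed intensity is background-subtracted and corrected for spatial trends within the array, per the file headers, and is not scaled between arrays. The deposited value table holds log2 values for 26205 gene symbols, and its way of joining probes per gene is not given in the sources used here. Its 75th percentile lay between 0.0032 and 0.00898 on each array, and its correlation with the log2 processed signal of the same array, across symbols, lay between 0.985 and 0.992. Its direction and log base were borne out by that comparison. The column medians ran from -3.18 to -2.89 (healthy replicates 1 and 2 at -2.93 and -3.18, ALA at -2.89 and -3.15, fish oil at -2.93 and -3.10, n-6 at -3.14 and -3.15).

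Control spots and spots marked as outliers were left out, and repeated spots of a probe were averaged. The main setting was log2 of the processed signal minus the 75th percentile of each array. A probe entered where it was well above background on both arrays of at least 1 group, which 20793 of 30367 probes met. A gene was represented by its probe with the highest mean signal. This left 18169 genes, of which 13171 had a name. Probes were named through a table of rat RefSeq genes of the GRCr8 assembly, used for names only. It named 18355 probes by accession, 194 by another accession, 2758 by the file's own symbol and 422 by a synonym, while 8638 matched nothing and kept the file's name. Probe positions are those of the files, on the rn4 build. For 2362 genes more than 1 probe passed the filter.

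Each of the 6 comparisons between groups was fitted with limma 3.58.1 in R 4.3.3, with all 8 arrays sharing 1 estimate of the spread (4 residual and 3.02 prior degrees of freedom). Benjamini-Hochberg adjustment was used over all genes tested, at a threshold of 0.05. For 36 gene lists, fixed before the data were examined, limma's camera tested whether a list moved relative to the other genes, with a preset correlation between genes of 0.01 and again with the correlation estimated from the arrays. limma's fry tested whether a list moved at all. List members were also adjusted over the list alone.

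Genes are named by a rule fixed at the same time. For ALA against n-6, fish oil against n-6 and n-6 against healthy, these are up to 10 rises and 10 falls with a symbol, an adjusted p under 0.05, no overlap of the arrays and signal well above background on at least 1 array of each group. For the other 3 comparisons the number is 5 and 5. Where none passed in a direction, the 3 smallest unadjusted p are given as not passing. Genes not well above background on either array of 1 group add up to 3 per direction, and each list discussed up to 4 members past the threshold adjusted over that list, or, where none passes, up to 2 with the highest signal. Loci with only a predicted number are counted but not named, and some genes that the rule selects are not reported. For a gene not well above background on any array of a group, the fold is a bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Where the probe's own signal is the higher, the bound equals the measured fold. It allows for signal near background and not for the spread between arrays.

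The test was tried on 20 simulated sets of 18169 genes with the real means and spread, for ALA against n-6 with 200 changed genes. It recovered 0.149% of changes of 1 on the log2 scale, 19.1% of changes of 2 and 69.8% of changes of 4, with 2.3 false calls per set. For fish oil against n-6, lists shifted by 1 were found in 91.7% of cases with the preset correlation and 35% with the estimated one. False lists numbered 0.2 and 0 per set, in simulated genes that vary independently.

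Signal limits precision here. The 75th percentile of the processed intensity was 175 on fish oil replicate 1 and 393 to 693 on the others. On that array 59.5% of spots were well above background, against 65.2% to 73.7% elsewhere. The median coefficient of variation of repeated spots ran from 4.33% on n-6 replicate 1 to 8.41% on n-6 replicate 2. No spot was saturated (0 on each array). Alternatives tried were normexp background correction (offset 50), quantile normalization, median centring, other filters on dim probes, the deposited value table, a fit of only the groups compared, a replicate block, an intensity trend with a robust prior, the mean of a gene's probes, a stricter fold change, and leaving out each array. Normexp keeping the probes of the main setting was added after seeing the data.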

Results

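Gene expression was measured in the colon of rats in 4 groups: healthy animals on sunflower oil, and animals with DSS colitis fed sunflower oil rich in n-6 fatty acids, alpha-linolenic acid (ALA, a plant n-3 fatty acid), or fish oil, which carries long-chain n-3 fatty acids. Each group had 2 arrays (n = 2 throughout), and their number limits the precision. Levels are log2 signals relative to the 75th percentile of their array. The study asked how each n-3 diet changed colitis against the n-6 diet, and its title speaks of different gene sets. Of the 8 arrays, fish oil replicate 1 alone correlated best with its own replicate (r = 0.971 for the fish oil pair, across genes, which are not independent replicates). The other 7 correlated best with an array of another group, and the n-6 replicates correlated least of the 4 pairs (r = 0.948). List calls below use camera's preset correlation. With an estimated correlation 0 of 36 lists passed in each comparison.

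The comparison of n-6 colitis with healthy colon shows what differed with colitis on the sunflower oil diet. Globins and Alas2 were far higher in n-6 colitis and Ahsp, which stabilises alpha globin, rose by 1.32 adjusted over the red cell list alone, while 12 other red cell genes had a median difference of -0.147. Hba-a1, a globin, had a level of 6.78 ± 0.394 (SD) in n-6 colitis and 1.88 ± 0.0994 in healthy colon. The globins Hba-a1, Hbb, Hbb-b1 and Hbe2 rose by 4.90, 4.64, 5.30 and 5.31 on the log2 scale (SE 0.311, 0.315, 0.36 and 0.397; limma adjusted p = 0.00949 for the first 3 and 0.0136 for Hbe2). Alas2, the red cell enzyme of haem synthesis, was at least 46.4-fold higher (adjusted p = 0.0398), being not well above background in healthy tissue. Fosl1, an AP-1 transcription factor, rose by 3.67 (SE 0.35, adjusted p = 0.0398) and was well above background on 1 of 2 healthy arrays. Cyp1a1, a xenobiotic-metabolising enzyme, was at least 15.6-fold lower and not well above background in n-6 colitis (adjusted p = 0.0314). The globin probes lie on chromosome 10 (Hba-a1, 15584360 to 15584419) and chromosome 1 (Hbb, 161584872 to 161584931; Hbb-b1, 161597660 to 161597719; Hbe2, 161648636 to 161648695) of rn4. Near-identical globin genes can bind each other's probes, so the assignment to single globins is uncertain. A further probe of Hbb was also higher but did not pass (adjusted p = 0.062 over all probes).

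**Figure D1:**
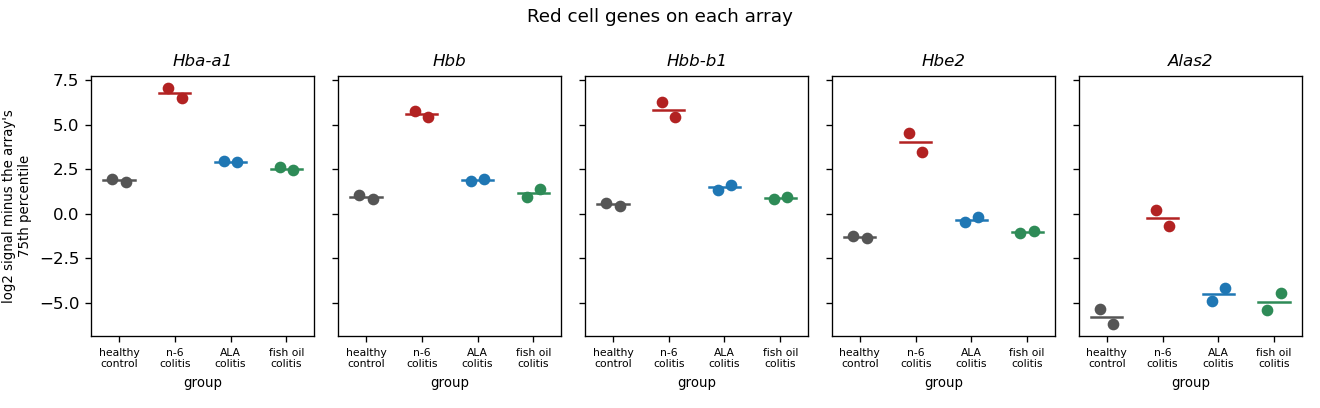
Levels of 5 red cell genes on each array, by group on the horizontal axis, as log2 signal minus the array's 75th percentile on the vertical axis, with single arrays as points and the mean of 2 as lines. For each gene both n-6 arrays sit above all other arrays, with Hba-a1 averaging 6.78 in n-6 colitis and 1.88 in healthy colon.

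Of 18169 genes, 7 changed between n-6 colitis and healthy colon, 6 higher and 1 lower, all named above. An unadjusted p under 0.05 was reached by 2601 genes, where 908 are expected by chance (1421 without healthy replicate 2, 3896 without n-6 replicate 2). The arrays of the groups did not overlap for 45.5% of genes, against 33.3% by chance. The count was 69 with normexp, 29 with an intensity trend and robust prior, and 13 with median centring. It was 0 when healthy replicate 1 or 2, fish oil replicate 1 or 2, or n-6 replicate 1 was left out, and 24 without n-6 replicate 2, 8 higher and 16 lower.

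Several lists of inflammatory genes were higher in n-6 colitis, but T cell markers and MHC class II genes did not pass as lists. The interferon response list was lower (camera adjusted p = 0.000714), a call lost without n-6 replicate 1 (median -0.11). B cell and lymphoid follicle markers rose, calls also lost without n-6 replicate 1 (medians 0.067 and 0.905). Cytokines and chemokines rose as a group (median log2 difference 1.08 over 24 genes; camera adjusted p = 0.00464, and adjusted p = 0.48 with an estimated correlation). Adjusted over the list alone, 9 members rose and 3 fell, while 0 passed over all genes. The neutrophil-attracting chemokines Cxcl2 and Cxcl3 rose by 5.75 and 5.37, and the interleukin-1 antagonist Il1rn by 3.16 (SE 0.889, 0.981 and 0.421). Interferon gamma (Ifng) and the interferon-induced chemokines Cxcl9 and Cxcl11 were the 3 that fell. Neutrophil genes rose as a group (median 1.82 over 15; adjusted p = 1.58e-07, and adjusted p = 0.404 with an estimated correlation). Of these, 8 rose adjusted over the list alone, among them the calprotectin subunits S100a8 (3.63, well above background on 1 of 2 healthy arrays) and S100a9 (2.62). Macrophage markers rose as a group (median 0.97 over 12; adjusted p = 1.47e-06, and adjusted p = 0.277 with an estimated correlation). Of these, 7 rose adjusted over the list alone, including the scavenger receptor Cd163 (2.88) and Cd68 (1.95). fry called this list and the red cell list (adjusted p = 0.0127 and 0.00197). The list of NF-kB signalling and endothelial adhesion genes rose (camera adjusted p = 0.00464, and adjusted p = 0.48 with an estimated correlation). That call was lost without healthy replicate 1 (median 0.37). In it the leukocyte adhesion molecule Selp rose by 4.72 adjusted over the list alone, and Sele, not well above background in healthy tissue, was at least 8.97-fold higher.

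Matrix remodelling genes had the smallest camera p of the 36 lists (median 1.39 over 28 genes; adjusted p = 2.98e-10, and adjusted p = 0.404 with an estimated correlation). Adjusted over the list alone, 12 rose and 0 fell, among them the protease inhibitor Timp1 (3.70, SE 0.436). Mmp2 rose by 1.81, while its other probe gave 0.90. Fibroblast markers rose too (camera adjusted p = 0.00991), so a differing share of fibroblasts is not excluded. That call was lost without healthy replicate 1 (median 0.41) or n-6 replicate 1 (0.49). The red cell list had a median of 4.77 over 6 genes (adjusted p = 4.03e-08, and adjusted p = 0.277 with an estimated correlation), with 5 rising adjusted over the list alone and 4 over all genes. Eicosanoid pathway genes did not move as a list (median 0.21, adjusted p = 0.356). Within it 4 rose and 3 fell adjusted over the list alone. The phospholipase Pla2g4a and the prostaglandin receptor Ptger2 rose by 1.74 and 1.68, and the prostaglandin-degrading Hpgd fell by 1.78.

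Lists of absorptive colonocytes and tight junctions were lower, calls lost without n-6 replicate 1 (medians -0.37 and 0.02; adjusted p = 0.409 and 0.603), and goblet cell genes did not move as a list. Absorptive colonocyte genes fell as a group (median -1.53 over 27; adjusted p = 0.000459, and adjusted p = 0.48 with an estimated correlation), with 0 members passing adjusted over the list alone. Genes of fatty acid oxidation and PPAR targets fell (median -0.73 over 35; adjusted p = 0.000459, and adjusted p = 0.579 with an estimated correlation), 6 members falling and 2 rising adjusted over the list alone. The peroxisomal enzyme Ehhadh had a log2 change of -3.29 and the mitochondrial Acadm of -1.71. Tight junction genes fell (median -0.41 over 21; adjusted p = 0.00991, and adjusted p = 0.579 with an estimated correlation), with 4 passing adjusted over the list alone. Among them Cgn fell by 2.09, and Cldn2, not well above background in n-6 colitis, was at least 18-fold lower. In the goblet cell list (camera adjusted p = 0.333), adjusted over the list alone 2 rose, Retnlb (6.86, SE 1.86) and Tff3 (2.60), while 4 fell. Retnlb lay far apart on healthy replicates 1 and 2 (-0.9 and -6.3), so the size of its rise is uncertain. Pck1, an enzyme of gluconeogenesis and glyceroneogenesis in a list of adipocyte markers that did not pass (adjusted p = 0.128), fell by 3.83 adjusted over the list alone.

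Of the 36 lists, 12 rose and 7 fell between n-6 colitis and healthy colon. Without n-6 replicate 1, 9 of these 19 kept their call. The colonocyte (median -0.37, adjusted p = 0.409), fatty acid oxidation (-0.23, 0.173) and tight junction lists (0.02, 0.603) did not. The last pair was also lost without healthy replicate 2 (adjusted p = 0.105 and 0.127). The cytokine (median 0.66, adjusted p = 0.0258), neutrophil (1.19, 2.51e-05), macrophage (1.07, 4.67e-06), matrix (0.86, 2.7e-06) and red cell lists (4.54, 1.13e-08) were kept. Without n-6 replicate 2 the medians were 1.67 for cytokines, -1.11 for fatty acid oxidation and -1.05 for tight junctions. Of 51 named gene calls, those of Cxcl2, Il1rn, Selp, Timp1 and Pck1 alone held with every array left out in turn. These were judged over their lists alone. Genes that had passed over all genes, the globins among them, were judged over all genes.

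ALA was compared with n-6 colitis to learn what ALA changes in colitis. The same globins were lower in ALA colitis: the log2 changes were -4.35 for Hbb-b1, -4.34 for Hbe2, -3.86 for Hba-a1 and -3.70 for Hbb (SE 0.36, 0.397, 0.311 and 0.315; limma adjusted p = 0.0324, 0.0427, 0.0324 and 0.0324). Lpal2, not well above background in n-6 colitis, was at least 16.7-fold higher (adjusted p = 0.0324). The red cell list had a median of -3.78 over 6 genes (camera adjusted p = 4.64e-14, and adjusted p = 0.201 with an estimated correlation; fry adjusted p = 0.00435). Adjusted over the list alone 5 of its genes fell, while 3 passed over all genes. Alas2 (-4.27) was among the former, well above background on 1 of 2 ALA arrays. Further probes of Hba-a1 and Hbb gave -3.70 and -2.57 and did not pass (adjusted p = 0.209 and 0.745 over all probes).

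Of 18169 genes, 5 changed between ALA and n-6 colitis, 1 higher and 4 lower, and 1054 had an unadjusted p under 0.05 against 908 expected (843 without ALA replicate 1, 1849 without n-6 replicate 2 and 514 with normexp). The arrays did not overlap for 30% of genes, against 33.3% by chance. With a replicate block the number of changed genes was 0. The count was 0 with each of the 8 arrays left out in turn, with no filter, with the deposited value table, with the mean of a gene's probes and with only the groups compared. The log2 change of Hbb-b1 stayed between -4.78 and -3.93 in 19 alternatives, with adjusted p from 0.00312 to 0.387.

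Matrix remodelling genes fell as a group (median -0.82 over 28; adjusted p = 9.53e-08, and adjusted p = 0.521 with an estimated correlation). Timp1 fell by 1.98 and the collagen Col5a1 by 1.18 adjusted over the list alone. Fibroblast markers fell too (median -0.55 over 15; adjusted p = 6.34e-05, and adjusted p = 0.26 with an estimated correlation), with 0 members passing adjusted over the list alone. Other markers of the gut wall fell as well, those of enteric neurons and glia (median -0.63; adjusted p = 8.54e-05, and adjusted p = 0.598 with an estimated correlation) and smooth muscle (-0.36; adjusted p = 0.00153, and adjusted p = 0.598 with an estimated correlation), so a differing share of wall tissue is not excluded. The neuron call was lost without n-6 replicate 2 (-0.23, adjusted p = 0.189), and the smooth muscle call without ALA replicate 2 (-0.05, adjusted p = 0.112) or n-6 replicate 1 (-0.31, adjusted p = 0.0799). The smooth muscle median was -0.73 without ALA replicate 1 and -0.65 without n-6 replicate 2. Without ALA replicate 2 the medians were -0.41 for matrix and -0.23 for fibroblast genes, and without n-6 replicate 1 -0.46 for matrix genes, and these calls held. Pla2g4a and Ptger2 fell by 1.86 and 1.57 adjusted over the eicosanoid list alone. The call of that list (adjusted p = 0.0492, and adjusted p = 0.474 with an estimated correlation) was lost with any array left out (adjusted p from 0.053 to 0.157). Pck1 rose by 2.57 adjusted over the adipocyte list alone. Cytokines and chemokines did not pass (median -0.43, adjusted p = 0.0671).

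Neutrophil genes and macrophage markers fell with ALA (median -0.42 over 15 and -0.33 over 12; adjusted p = 0.0299 and 0.0247, and adjusted p = 0.598 and 0.521 with an estimated correlation). The neutrophil call was lost without ALA replicate 1 (median -0.76, adjusted p = 0.0982), ALA replicate 2 (-0.11, 0.0564) or n-6 replicate 1 (0.18, 0.761), and its median was -0.90 without n-6 replicate 2. The macrophage call was lost without ALA replicate 1 (adjusted p = 0.0968), ALA replicate 2 (0.0501), n-6 replicate 1 (0.0956) or n-6 replicate 2 (0.095).

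Colonocyte genes rose with ALA (median 0.82 over 27; adjusted p = 0.0304, and adjusted p = 0.673 with an estimated correlation). Without n-6 replicate 1 their median was -0.48 (adjusted p = 0.0579), and the call was also lost without ALA replicate 1 or 2 (adjusted p = 0.0982 and 0.0564). Without n-6 replicate 2 it was 1.43. Cell cycle genes rose (median 0.64 over 29; adjusted p = 0.0128, and adjusted p = 0.817 with an estimated correlation), but their median was -0.79 without n-6 replicate 2 (adjusted p = 1.4e-05) and 0.19 without ALA replicate 2 (adjusted p = 0.977). It was 2.01 without n-6 replicate 1 and 1.02 without ALA replicate 1. Of the 36 lists 6 rose and 12 fell. Of these 18, 8 kept their call without n-6 replicate 1 and 7 without ALA replicate 1, the matrix and fibroblast lists among both. Of 13 named gene calls, that of Alas2 alone held with every array left out in turn. It was judged over the red cell list alone, while the globins and Lpal2 were judged over all genes.

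Fish oil was compared with n-6 colitis in the same way. The globins were again lower: the log2 changes were -5.04 for Hbe2, -4.95 for Hbb-b1, -4.44 for Hbb and -4.26 for Hba-a1 (SE 0.397, 0.36, 0.315 and 0.311; limma adjusted p = 0.0155 for Hbe2 and 0.0116 for the others). Lpal2 and Slurp2, a secreted Ly6-family protein, were at least 18.8-fold and at least 18-fold higher (adjusted p = 0.0116 and 0.0274), being not well above background in n-6 colitis. The red cell list had a median of -4.35 over 6 genes (camera adjusted p = 5.48e-09, and adjusted p = 0.465 with an estimated correlation; fry adjusted p = 0.00247). Adjusted over the list alone 5 of its genes fell, while 3 passed over all genes. Further probes of Hba-a1 and Hbb gave -4.40 and -4.24 and did not pass (adjusted p = 0.0737 for each over all probes).

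Of 18169 genes, 7 changed between fish oil and n-6 colitis, 3 higher and 4 lower, 1 of them without a gene name. An unadjusted p under 0.05 was reached by 2175 genes against 908 expected, but by 851 without n-6 replicate 1, 1052 without fish oil replicate 1 and 4255 without n-6 replicate 2. The excess over chance was thus gone without n-6 replicate 1 and small without fish oil replicate 1, so it depended on each of these arrays. The arrays did not overlap for 46.7% of genes against 33.3% by chance. The count was 0 without n-6 replicate 1, either fish oil array or either healthy array, and with only the groups compared. It was 4 with normexp and where all 8 arrays had to be well above background.

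The cytokine list, the neutrophil list and the list of NF-kB signalling and endothelial adhesion genes were lower with fish oil. Macrophage markers did not pass (median -0.34, camera adjusted p = 0.0725). Cytokines and chemokines fell as a group (median -1.15 over 24; adjusted p = 9.61e-05, and adjusted p = 0.511 with an estimated correlation). Adjusted over the list alone 5 fell, while 0 passed over all genes. The log2 changes were -3.38 for Cxcl2, -2.37 for the macrophage chemokine Ccl3, -2.35 for Ccl2 and -2.03 for interleukin-1 beta (Il1b). Neutrophil genes fell (median -0.86 over 15; adjusted p = 0.000635, and adjusted p = 0.511 with an estimated correlation), with 0 members passing adjusted over the list alone. The NF-kB and adhesion list fell (camera adjusted p = 0.00558, and adjusted p = 0.511 with an estimated correlation), a call lost without fish oil replicate 2 (median -0.29). Of it 4 fell adjusted over the list alone, including Selp (-3.99) and Icam1 (-1.75). Matrix genes fell (median -1.19 over 28; adjusted p = 4.39e-09, and adjusted p = 0.511 with an estimated correlation), with Timp1 (-2.15) among 3 passing adjusted over the list alone. Fibroblast markers fell too (camera adjusted p = 0.0235), so a differing share of fibroblasts is not excluded. That call was lost without fish oil replicate 2 or n-6 replicate 1 (median -0.34 for each).

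Among lipid genes, Angptl4, an inhibitor of lipoprotein lipase, fell by 3.44 and Pck1 rose by 2.22, each adjusted over its list alone. Pla2g4a and Ptger2 fell by 1.75 and 1.57 adjusted over the eicosanoid list alone, a list that did not pass (adjusted p = 0.0925). Colonocyte genes rose (median 1.31 over 27; adjusted p = 0.000131, and adjusted p = 0.511 with an estimated correlation) and B cell markers fell (median -2.41 over 15; adjusted p = 0.000146, and adjusted p = 0.513 with an estimated correlation). Cell cycle genes fell (median -1.51 over 29; adjusted p = 3.75e-06, and adjusted p = 0.513 with an estimated correlation). Of the 36 lists 6 rose and 11 fell. Without n-6 replicate 1, 6 of these 17 kept their call, each of them a fall. The cytokine (adjusted p = 9.18e-05), neutrophil (0.0278), matrix (3.18e-07, median -0.72) and red cell lists (5.12e-12) were kept, and the colonocyte (0.189, median 0.43), B cell (0.085, median -0.69) and cell cycle lists (0.856, median -0.01) were not. Without n-6 replicate 2 the medians were -1.79 for cytokines, -1.47 for neutrophil genes, -4.12 for B cell markers and -2.84 for cell cycle genes. Of 26 named gene calls, that of Alas2 alone held without n-6 replicate 1 (log2 change -4.68, well above background on 1 of 2 fish oil arrays). It was judged over the red cell list alone, while the globins, Lpal2 and Slurp2 were judged over all genes.

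**Figure D2:**
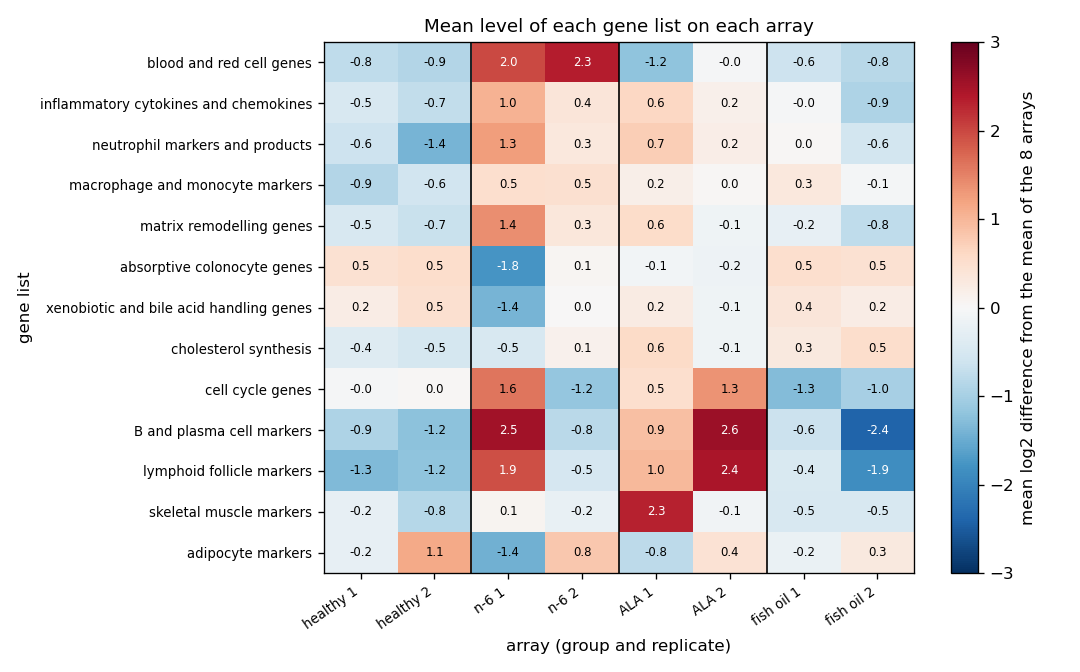
Mean level of 13 gene lists (vertical axis) on each of the 8 arrays (horizontal axis), as the log2 difference from the mean of the arrays, shown by colour and number. Red cell genes are high on both n-6 arrays (1.97 and 2.35), while B cell markers differ between the n-6 arrays (2.52 and -0.81).

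Whether the n-3 diets act on different genes was tested by overlap and by comparing them directly. Hbb, Hbb-b1, Hba-a1 and Hbe2 were lower, and Lpal2 higher, in both comparisons with n-6 colitis, so 5 genes were shared. The count was 0 with each of the 8 arrays left out in turn, and with no filter, the value table, the replicate block, the mean of a gene's probes or only the groups compared. Unchanged simulated groups against the same n-6 arrays shared 0 in 100 simulations, and independent lists would share 1.65e-04 higher and 8.81e-04 lower genes. With an unadjusted p under 0.05 the genes moving the same way numbered 465, against 268.7 simulated and 63.1 for independent lists. That count was 278 without n-6 replicate 1, 1441 without n-6 replicate 2, 297 without ALA replicate 1, 298 and 255 without fish oil replicates 1 and 2, and 304 with normexp, and the simulation was not repeated for these. The fold changes correlated at 0.371 across genes, against 0.496 simulated. Their covariance was 0.191 against 0.195 simulated, a difference of -0.0041. Both comparisons use the same 2 n-6 arrays, as the simulated groups did. The simulation and the independent lists take genes to vary independently, while real genes can move together, as the shared globins did. The simulated and independent counts therefore cannot show whether the overlap exceeds chance.

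Between ALA and fish oil colitis directly, B and plasma cell markers were higher with ALA (median 3.10 over 15; camera adjusted p = 1.28e-06, and adjusted p = 0.848 with an estimated correlation). Of these, 8 passed adjusted over the list alone. The B cell receptor subunits Cd79b and Cd79a, not well above background with fish oil, were at least 55.1-fold and at least 12.8-fold higher. The other probe of Pou2af1, a B cell coactivator, gave 1.64 where the first gave 4.76. Cell cycle genes were higher with ALA (median 2.24 over 29; adjusted p = 1.44e-11, and adjusted p = 0.848 with an estimated correlation). The matrix proteases Mmp12 and Mmp7, not well above background with fish oil, were at least 11.6-fold and at least 7.08-fold higher, adjusted over a list that did not pass (adjusted p = 0.141). Of 7 named gene calls in these lists, 0 held with every array left out in turn.

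limma called 0 single genes between ALA and fish oil (smallest adjusted p = 0.306), while 1744 had an unadjusted p under 0.05 against 908 expected (1092 without fish oil replicate 1, and 699 with normexp, below that expected). Quantile normalization called 1, and so did the fit without ALA replicate 1. Among genes with a symbol the smallest p values, which did not pass, belonged to Tnfrsf18, Izumo1r and Rln1 (higher with ALA) and Slurp2, Hmmr and Ephb1 (lower with ALA), with adjusted p from 0.444 to 0.476.

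Each n-3 group was also set against healthy colon. Cholesterol synthesis genes rose in both (median 0.70 with ALA and 0.86 with fish oil over 24; camera adjusted p = 1.09e-05 and 1.08e-11, and adjusted p = 0.665 and 0.83 with an estimated correlation). Macrophage markers rose in both (median 0.99 and 0.73 over 12; adjusted p = 2.26e-05 and 3.81e-06, and adjusted p = 0.665 and 0.515 with an estimated correlation). For ALA the medians without its replicate 1 were 0.32 for cholesterol and 0.53 for macrophage genes, and 1.08 for cholesterol genes without its replicate 2. For n-6 colitis against healthy colon the cholesterol list did not pass, but its median was 0.55 without n-6 replicate 1. A cholesterol rise particular to the n-3 diets is thus not shown. With ALA, neutrophil genes (median 1.44) and B cell markers (3.28) rose (adjusted p = 2.82e-06 and 1.72e-06, and adjusted p = 0.665 for each with an estimated correlation). Neutrophil genes also rose with fish oil (median 0.76; adjusted p = 0.00115, and adjusted p = 0.83 with an estimated correlation), a call lost without fish oil replicate 1 (0.33, adjusted p = 0.0506), and by 0.32 without healthy replicate 2. With ALA, Cxcl2 and Cxcl3 rose by 5.08 and 4.51, and Slc7a11 and Hmox1, targets of NRF2, by 3.98 and 2.25, adjusted over their lists alone. With fish oil, the cytokine list had a median of 0.08 while camera placed it below the other genes (adjusted p = 0.776). Cell cycle genes fell (median -1.20; adjusted p = 7.85e-08, and adjusted p = 0.83 with an estimated correlation), and neuron and glia markers rose (median 0.59; adjusted p = 0.000332, and adjusted p = 0.83 with an estimated correlation), by 0.89 without fish oil replicate 2. The stem cell genes Ascl2 and Axin2 had log2 changes of -3.08 and -2.54, passing over their list alone, Axin2 being well above background on 1 of 2 fish oil arrays. Their list fell (median -0.54; adjusted p = 0.00372, and adjusted p = 0.83 with an estimated correlation), with medians of -1.65 without healthy replicate 2 and -0.97 without fish oil replicate 1, and was lost without healthy replicate 1 (adjusted p = 0.066). Cyp1a1 was not well above background in either group, at least 13.4-fold lower with ALA (adjusted p = 0.304) and at least 8.73-fold lower with fish oil (adjusted p = 0.261), passing over its list alone.

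limma called 0 genes for ALA against healthy colon (1188 with an unadjusted p under 0.05, 908 expected; 710 without healthy replicate 2 and 644 with normexp) and 0 for fish oil (709; 360 without fish oil replicate 1, 1150 without its replicate 2 and 390 with normexp). The fit without ALA replicate 1 called 1 gene for ALA. For fish oil, quantile normalization called 1 and median centring 2. Slurp2 had the smallest p with fish oil, at least 19.5-fold higher (adjusted p = 0.109), and did not pass. Also among the 3 smallest p in a direction without passing were Rln1, Izumo1r and Ftx (higher) and Cyp1a1, Ly49i2 and Tex15 (lower) with ALA, and Hmmr and Cngb3 (higher) and Cyp1a1, Rbm14 and Dcdc2 (lower) with fish oil. Rbm14 turned to 0.41 with normexp. Ftx, not passing with ALA, gave 7.29 by its first probe and 1.97 by its other, and Dcdc2, not passing with fish oil, -3.59 and -0.94. Of the 36 lists 11 rose and 6 fell with ALA, and 4 rose and 5 fell with fish oil. Of the named gene calls, 0 of 10 with ALA and 0 of 7 with fish oil held with every array left out in turn. Median and mean of a list differed in sign in 1 list for fish oil against n-6, 3 for n-6 against healthy, 3 for ALA against fish oil, 3 for ALA against healthy and 5 for fish oil against healthy. These were lists that did not pass, such as adipocyte, enteroendocrine, tuft and squamous markers, and in 0 lists that passed did camera go against the median.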

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

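The tests of follicle content and of cell cycle genes in this part were chosen after the results were seen. ALA and fish oil colitis, each set against the same n-6 arrays, differed in 10 gene lists by a direct camera test of the difference. With an estimated correlation 0 of these passed (adjusted p = 0.848 for each). Cell cycle genes (median log2 difference 2.24), B and plasma cell markers (3.10), lymphoid follicle markers (2.59), skeletal muscle markers (1.58), cytokines and chemokines (0.97) and T cell markers (0.62) were higher with ALA. Enteric neuron and glia markers (-0.87), colonocyte genes (-0.72), tight junction genes (-0.49) and smooth muscle markers (-0.45) were lower. With ALA replicate 1 left out 8 of these calls held, and 5, 9 and 5 without ALA replicate 2, fish oil replicate 1 and fish oil replicate 2. Cell cycle, B cell and neuron lists held in each of these and in all 19 alternative settings. Of the other lists lower with ALA, colonocyte genes held in 13 of 19, smooth muscle markers in 12 and tight junction genes in 11. T cell markers held in 9, and the other lists higher with ALA in at least 17. Skeletal muscle markers were lost without ALA replicate 1 (0.45, adjusted p = 0.201; 2.40 without ALA replicate 2), cytokines without fish oil replicate 2 (0.44, adjusted p = 0.402) and follicle markers without ALA replicate 2 (2.13, adjusted p = 0.0752). T cell markers were lost without ALA replicate 2 (0.09, adjusted p = 0.945) fish oil replicate 1 (0.0506) or 2 (0.124), or either n-6 array (0.105), and were at 1.26 without ALA replicate 1. Colonocyte genes were lost without ALA replicate 2 (median -0.72) or fish oil replicate 2 (-0.82). Tight junction genes were lost without ALA replicate 1 (median -0.67), ALA replicate 2 (-0.29) or fish oil replicate 2 (-0.60). Smooth muscle markers were lost without ALA replicate 2 (median -0.17), fish oil replicate 2 (-0.13) or either n-6 array (-0.45), so 8 calls held without each n-6 array.

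B cell, follicle and cell cycle genes moved apart between the diets, and samples may differ in how many lymphoid follicles they caught. The 2 n-6 arrays lay apart by 3.33 on the B cell markers, as much as ALA and fish oil did (3.26). The level of this list thus varied that far between arrays of 1 diet. Follicle content itself was not measured, and the gap does not separate sampling from an effect of diet. Cell cycle genes brought by follicles cannot be told apart from other cycling cells, since their r with B cell markers was 0.857 (exact permutation p = 0.0105, adjusted over 4 relations 0.014; Spearman rho 0.571, p = 0.151), but 0.518 (exact permutation p = 0.347) without ALA replicate 2 and n-6 replicate 1, so the relation rests on those arrays. An effect of diet on follicles or cell division stays open and was not tested.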

How the results depend on the processing

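Named genes kept their direction wherever an alternative gave a value (79 of 132 where all 8 arrays needed signal) except for 4 given below, while many calls did not hold. Normexp keeping the probes of the main setting was chosen after seeing the data and gave the same counts as planned normexp. The cause was not tested, except that fits of only the compared groups or with an array left out have fewer samples. With normexp, genes changed numbered 4 for ALA versus n-6 (0 higher, against 1 of 5), 4 for fish oil versus n-6 (0 higher, against 3 of 7) and 69 (52 higher, 17 lower) for n-6 versus healthy, where 5 of the 7 genes called before stayed, against a split of 6 and 1. Quantile normalization gave 1 for ALA versus fish oil, 1 for fish oil versus healthy and 6 lists for ALA versus fish oil. Median centring gave 13 for n-6 versus healthy and 2 for fish oil versus healthy. With no filter the counts were 0 for ALA versus n-6, 4 for n-6 versus healthy and 0 shared by the diets. Requiring signal on all 8 arrays gave 4 for fish oil versus n-6. The value table gave 0 for ALA versus n-6, 2 for n-6 versus healthy and 0 shared. Only the 2 groups compared gave 0 for ALA versus n-6, fish oil versus n-6, n-6 versus healthy and shared genes. The intensity trend and robust prior gave 29 for n-6 versus healthy. The mean of a gene's probes gave 0 for ALA versus n-6 and 0 shared. An estimated correlation gave 0 lists in ALA versus n-6, fish oil versus n-6, n-6 versus healthy and ALA versus fish oil. Labels number replicates in each group, and deviations of same-numbered arrays correlated from -0.168 (n-6 with fish oil) to 0.47 (healthy with ALA). The numbers thus do not pair the samples across all groups, but a pairing of some groups was not excluded. The replicate block gave 0 for ALA versus n-6, 13 for n-6 versus healthy and 0 shared. Leaving out each array gave 0 to 0 for ALA versus n-6, 0 to 6 for fish oil versus n-6, 0 to 24 for n-6 versus healthy, 0 to 1 for ALA versus fish oil, 0 to 1 for ALA versus healthy, 0 to 0 for fish oil versus healthy and 0 to 0 shared. Lists then ranged from 12 to 21, 8 to 20, 12 to 19 and 5 to 14 for ALA versus n-6, fish oil versus n-6, n-6 versus healthy and ALA versus fish oil. A lone array is then assumed to vary like the other groups. Both normexp settings turned 4 named values of fish oil versus healthy, Rbm14 (0.41), Ppara (0.31), Ifng (0.28) and Ephb2 (0.0474). The median change of all genes was 0.233 for fish oil versus n-6, 0.104 for n-6 versus healthy, -0.179 for ALA versus fish oil and 0.239 for fish oil versus healthy with normexp, and -0.128 for ALA versus n-6, -0.12 for fish oil versus n-6 and 0.169 for n-6 versus healthy with median centring. The dim fish oil replicate 1 limits genes near background.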

Other observations

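The tests of a dim array and of a smaller share of epithelium in this part were chosen after the results were seen. Markers of tissue around the colon lining differed between single arrays. Skeletal muscle markers were at 2.30 on ALA replicate 1 and -0.10 on ALA replicate 2, relative to the mean of the arrays. Adipocyte markers were at 1.14 on healthy replicate 2 and -0.24 on healthy replicate 1, and at -1.45 and 0.82 on n-6 replicates 1 and 2.

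Red cell genes were high on both n-6 arrays, which blood brought along with the tissue may account for. Platelet genes, which blood also carries, had a median n-6 minus healthy difference of 0.595 over 10 genes, above 99.5% of 10000 random lists matched on signal. Of these, Pf4 was higher by 2.89 and Gp1bb by 1.43, and Nrgn was at -1.09. Without Selp, which another list holds and whose value had been seen, the median was 0.575 (above 98.9%). The random lists hold unrelated genes, while 12 of the 36 lists rose in this comparison. A list of genes that move together can exceed them without blood, so the platelet values do not show that blood was the cause. The 12 further red cell genes given next did not rise as a set. Globin probes binding each other's transcripts stay open: red cell genes other than globins had a median of -0.147 over 12 genes, under the bound set beforehand, but 5 were higher and 7 lower, so it was taken as undecided by a condition added after the value was seen, and Alas2 and Ahsp, which are no globins, rose. Bleeding from the inflamed colon, which the DSS groups share, was not tested apart from blood left in the sample.

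The n-6 replicates lay far apart, with n-6 replicate 1 at 99.2 on the first principal component and replicate 2 at 4.85. The tables argue against replicate 1 being dim or noisy, since its repeated spots varied least (4.33%) and its 75th percentile signal was 678, but noise on replicate 2, whose spots varied most (8.41%, 75th percentile 393), was not excluded. A smaller share of epithelium met the part of its test on epithelial genes. The median difference was -1.65 for 24 epithelial genes of a list other than the colonocyte list, near -1.84 for the colonocyte list. A smaller share as the whole cause is argued against only by a condition added after its values were seen. Lists of 10 other cell types moved apart by 5.17, from 3.31 for B cell markers to -1.86 for adipocyte markers, where the larger interquartile range was 2.59. No biological explanation other than the share of epithelium was tested, since both arrays carry the same group label.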
